A study of Homo sapiens with 11 samples.

How the data were processed

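The series holds 11 arrays of total RNA from Jurkat cells that express PD-1, kept for 18 hours with antibody-coated beads. Samples were grouped by their titles into 6 with beads against CD3, CD28 and PD-1 and 5 with beads against CD3 and CD28. The source name field writes CD38 where the titles and the design text write CD28, and the titles and the design text were followed. Per the labels' protocols, RNA was checked on a Bioanalyzer and cDNA was labelled with biotin using a Nugen FL-Ovation kit. The values deposited by the authors are intensity values, 1 per probe set and array, and the submitters' processing notes name RMA, a method that corrects background, normalizes quantiles and summarises probes. The version and settings of RMA are not given in the sources used here. The deposited intensities were on a linear scale, from 5.85 to an array maximum of 14342 to 14868, with 0 missing values, and their log2 was taken for all tests. RMA makes the distributions of the arrays alike, so a change in the total amount of RNA per cell cannot be seen in these values, and it compresses differences among dim probe sets.

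Gene names came from a platform annotation table, which can be old. Of 22277 probe sets 62 were controls, 19724 had 1 gene symbol, 568 had several and 1923 had none in that table. Through Entrez identifiers 19713 of the 1-symbol probe sets matched a RefSeq gene table of assembly GRCh38.p14, used for names only, and 0 were renamed. Probe sets with several symbols or none were not named. Each of the 12165 genes was represented by its probe set with the highest mean over all arrays, and 4505 genes had more than 1 probe set. The 27 bacterial probe sets without a target had mean log2 intensities from 2.86 to 3.55, and the 9076 genes above the highest of these are called above the no-target level.

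The groups were compared on the log2 scale with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no covariate, 2-sided, and Benjamini-Hochberg adjustment over genes with a threshold of 0.05. Lists of genes were tested with camera at a preset correlation of 0.01 against all other genes, and beside it with camera at an estimated correlation and with fry, adjusted over 29 lists. The level of a list on an array was the mean of its gene-centred log2 values, compared by an exact 2-sided permutation test over the 462 splits of the arrays, whose smallest p is 0.00216. Quality measures were compared by the same exact test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

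The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 12 largest rises and the 12 largest falls among genes past the threshold whose arrays all lie on the same side of the other group's mean, or, where fewer than 5 pass in a direction, the 5 with the smallest p. In every list it names at most 4 members past the threshold, or the 2 with the smallest p where 0 pass, and it always names CD3E, CD28, BATF, IL2, CD69, IL2RA and MYC. These parts gave 73 genes. Other genes of the named lists that the text mentions were chosen after their values were seen. The symbol CXCL8 stood beside 9 probe sets in the annotation table, some of which may not be that gene, and it is not reported alone. Some genes fixed in advance are not reported here.

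The procedure was tested on simulated data for this comparison, with 200 of 12165 genes changed. It recovered 26% of genes changed by 0.2 on the log2 scale, 84% at 0.3 and 100% at 0.5 and at 1, with 8 false calls and 0 calls of the wrong sign. Of 100 lists with no change 3 had an unadjusted p under 0.05, and 20 of 20 lists shifted by 0.1 did. The simulated genes were drawn independently, so camera was not tested on lists whose members move together. Estimated correlations within the real lists reached 0.25, so these rates need not hold for them at the preset of 0.01. Alternatives were a replicate block fixed or random, quantile normalization again, centring on array medians, the mean of all probe sets of a gene, every probe set by itself, a filter on level, an intensity trend with robust variances, array weights, a minimum log2 fold change of 0.5 and leaving out each array. Covariates of hybridisation controls and of 18S controls were added after seeing the data. Genomic coordinates were not used here.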

Results

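Gene expression was measured in a Jurkat line that expresses PD-1. Jurkat is an established human leukaemic T cell line, and PD-1 is an inhibitory receptor of activated T cells. The cells were kept for 18 hours with beads carrying antibodies to CD3 and CD28, which engage the T cell receptor complex and its main costimulatory receptor. In 6 samples the beads also carried an antibody to PD-1, and in the other 5 they did not. Each sample was hybridised to 1 array with 22277 probe sets, from which 12165 genes were tested. The median intensity of an array lay between 29.1 and 30.2, and the number of arrays limits the precision of every value. The labels number the replicates without saying whether they were separate cultures, so all p-values measure the spread between these samples, which can be technical.

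The single comparison asked which transcripts differ between beads with and without anti-PD-1, both carrying antibodies to CD3 and CD28. No samples were kept without stimulation or with anti-PD-1 alone. The response to CD3 and CD28 itself was therefore not measured, and a changed strength of it cannot be told apart from PD-1 engagement. The largest change was in GZMB, which encodes granzyme B, a protease of cytotoxic granules. Its intensity was 664 ± 54.5 (SD, n = 6) with anti-PD-1 beads and 288 ± 19.8 (SD, n = 5) without, a 2.31-fold rise. GBP1, an interferon-induced GTPase, rose 1.72-fold from 114 ± 9.82 to 197 ± 16.5, and ENPP1, an ectonucleotidase that hydrolyses extracellular ATP, rose 1.58-fold from 596 ± 50.4 to 938 ± 58.5 (SD, n = 5 and n = 6). IRF1, a transcription factor of the interferon response, rose 1.43-fold from 239 ± 30.1 to 342 ± 34.2. In total 28 genes were higher and 1 was lower with anti-PD-1 beads, a split that moved to 72 and 40 with an intensity trend and robust variances.

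The log2 fold change was 1.21 with a standard error of 0.062 for GZMB (limma, adjusted p = 2.1e-07), 0.79 with 0.067 for GBP1 (adjusted p = 8.23e-05) and 0.66 with 0.061 for ENPP1 (adjusted p = 0.000143). Behind these came PHLDA1 at 0.54, the galectin gene LGALS1 at 0.52, IRF1 at 0.52, the T cell adaptor SH2D2A at 0.50, the immunoproteasome subunit PSMB9 at 0.50, IFI35 at 0.49, the peptide transporter TAP1 at 0.48, the receptor-proximal adaptor LAT at 0.45 and the metalloproteinase inhibitor TIMP1 at 0.45. Adjusted p over these 12 genes ran up to 0.0232, the value of LAT. The 2 probe sets of LAT differed, since the dimmer one gave 0.10, and 4 dimmer ones of PHLDA1 gave 0.13 to 0.58. The dimmer probe set of GBP1 gave 0.42 (limma over all probe sets, adjusted p = 0.0628). That of ENPP1 gave 0.46 (adjusted p = 0.0613), so neither passed by itself. Probe sets without a symbol are not ranked here, and the largest rise among them was 0.99. NT5E, the ectoenzyme CD73 that makes adenosine from AMP, rose by 0.36 (adjusted p = 0.0136). MON1B was the gene that fell, from 138 ± 6.31 to 113 ± 5.77, by 0.29 on the log2 scale with a standard error of 0.046 (adjusted p = 0.0162). KANSL3 at -0.47 (adjusted p = 0.0545), BLMH at -0.20 (adjusted p = 0.0713), ZZZ3 at -0.30 (adjusted p = 0.0739) and EFEMP1 at -0.22 (adjusted p = 0.0751) were next by p and did not pass.

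**Figure D1:**
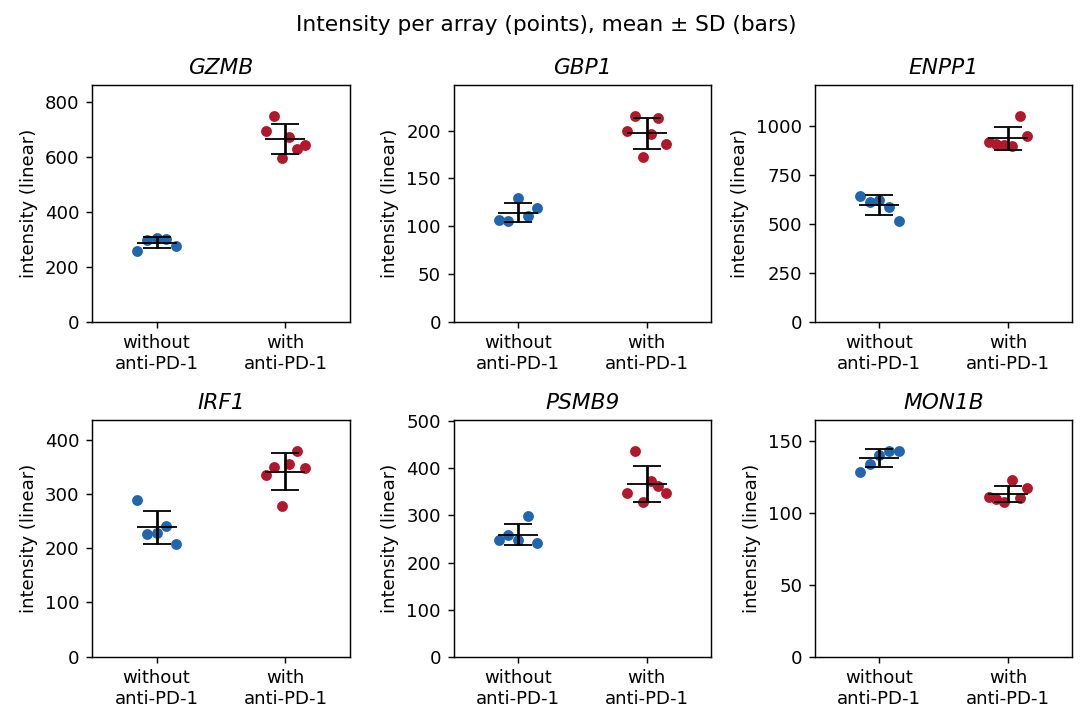
Linear intensity (y axis, starting at 0) of 6 genes on each array (points), with the mean and SD of each group (black bars), without anti-PD-1 (blue, n = 5) and with it (red, n = 6). GZMB means were 288 and 664, all 6 arrays with anti-PD-1 lay above all 5 without for GZMB, GBP1, ENPP1 and PSMB9, and MON1B means were 138 and 113.

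In 28 of the 29 genes past the threshold the arrays of the 2 groups did not overlap, and IRF1 was the exception. Such separation held for 213 of all genes, 1.75% where chance gives 0.433%, and 1419 genes had an unadjusted p under 0.05. All 29 lay above the level of bacterial probe sets that have no target. Leaving out 1 array at a time gave from 16 to 30 genes, and 14 of the 29 passed in all 11 such fits, among them GZMB, GBP1, ENPP1, LGALS1, PSMB9 and TAP1. Among the other named genes NT5E passed in 9 of these fits, HLA-E in 8, MON1B in 7, IRF1 in 6, STAT4 in 4, LAT in 3 and CST7 in 1. With the replicate number as a block 11 named genes did not pass, among them GZMA (adjusted p = 0.0588), TNFSF10 (adjusted p = 0.0622), TAP1 and TIMP1 (adjusted p at most 0.155). The labels do not say whether the numbers pair the samples. Restricting the test to genes at or above the median level gave 48 higher and 21 lower, so the count of lower genes rests on the variance model and on the filter.

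**Figure D2:**
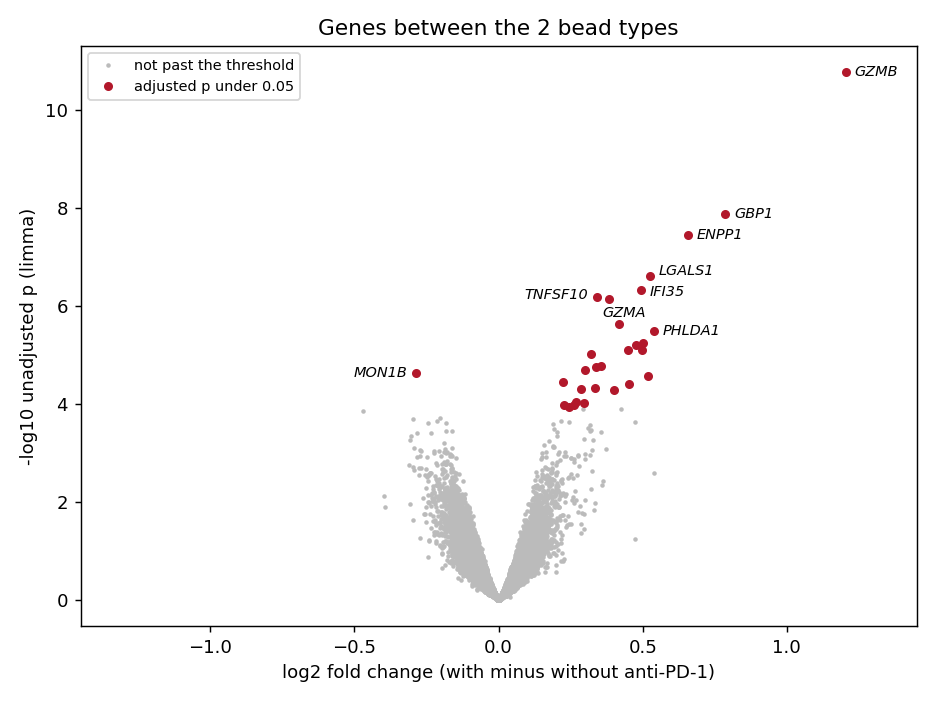
Log2 fold change (x axis, with minus without anti-PD-1) against -log10 of the unadjusted limma p (y axis) for each of 12165 genes, with the 29 genes of adjusted p under 0.05 in red and 9 of them named. GZMB stands furthest out at 1.21, and MON1B at -0.29 is the red point on the left.

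Among T cell activation genes, BATF, a basic leucine zipper factor of the AP-1 group, had an intensity of 381 ± 21.9 (SD, n = 6) with anti-PD-1 beads and 349 ± 13.4 (SD, n = 5) without. The log2 difference of 0.12 with a standard error of 0.047 did not pass over all genes (limma, adjusted p = 0.340). The early activation marker CD69 stood at 76.4 ± 10.1 against 63.6 ± 15.6 (log2 difference 0.28, adjusted p = 0.413). MYC stood at 2279 ± 82.7 against 2420 ± 172 (log2 difference -0.085, adjusted p = 0.511), and the receptor chain CD3E at 1179 ± 68.8 against 1192 ± 52.5 (log2 difference -0.017, adjusted p = 0.920). For CD28 the brightest probe set differed by 0.13 (adjusted p = 0.246), another by 0.13 and the remaining one by -0.026. IL2, at 10.4 ± 0.776 against 9.87 ± 0.337, and IL2RA, at 10.4 ± 0.722 against 11.8 ± 0.978, were not above the brightest no-target bacterial probe set, whose mean log2 intensity was 3.55, so no change in either could be read here.

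Gene groups fixed before the data were examined were then compared as sets. Interferon response genes were higher as a group: 26 of 30 measured members had a positive and 4 a negative fold change, and the mean shift was 0.18 on the log2 scale (camera, adjusted p = 3.49e-16). The list level per array was 0.083 ± 0.048 (SD, n = 6) with anti-PD-1 beads and -0.10 ± 0.011 (SD, n = 5) without, and an exact 2-sided permutation test gave p = 0.00216, the smallest that 462 splits allow (adjusted p = 0.0126). Over all genes tested 7 members rose, including GBP1, IRF1, PSMB9 and IFI35, and 14 rose when adjusted over the list alone. MHC and antigen presentation genes shifted by 0.093 (camera, adjusted p = 0.000224), with HLA-E, a non-classical class I molecule, rising by 0.34 from 1021 ± 56.6 to 1293 ± 86.0. Adjusted over the list alone 4 of its 13 measured members rose, and that list's call was lost with an adjusted p = 0.115 with an estimated correlation. Probe sets of HLA genes can share sequence with related family members, so the gene within the family is uncertain.

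The cytotoxic and NK cell list shifted by 0.12 (camera, adjusted p = 0.00108), and this rested on few members, since its median was 0.0059. GZMB, GZMA and the granule protease inhibitor CST7 rose over all genes tested, 3 of 18 measured members, and these and NKG7, 4 in all, rose when adjusted over the list alone. GZMA went from 1012 ± 17.8 to 1320 ± 79.6, a log2 change of 0.38 (adjusted p = 0.00124), and CST7 from 64.9 ± 2.22 to 78.2 ± 5.24, a change of 0.27 (adjusted p = 0.0437) that passed in 1 of 11 fits without an array. T helper lineage regulators shifted by 0.059 (camera, adjusted p = 0.00531, and adjusted p = 0.153 with an estimated correlation). STAT4, which transmits interleukin 12 signals, was the 1 member of 18 that passed, over all genes and adjusted over the list alone, rising by 0.22 (adjusted p = 0.0214), and it passed in 4 of 11 fits without an array. T cell receptor signalling components shifted by 0.041 (camera, adjusted p = 0.0220, and adjusted p = 0.0912 with an estimated correlation), with LAT past the threshold over all genes, though in 3 of 11 fits without an array, and 6 members higher and 1 lower of 34 when adjusted over the list alone. Apoptosis regulators shifted by 0.053 (camera, adjusted p = 0.0327, and adjusted p = 0.161 with an estimated correlation), where TNFSF10, the death ligand TRAIL, rose by 0.34 from 550 ± 21.8 to 696 ± 21.5 (adjusted p = 0.00124), and it was also the 1 member that rose when adjusted over the list alone.

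Thymocyte and quiescence genes were higher by 0.086 (camera, adjusted p = 6.44e-05), and 19 of 22 measured members had a positive fold change. IL7R, the interleukin 7 receptor chain, differed by 0.33 (adjusted p = 0.119) and CD1C by 0.18 (adjusted p = 0.119); 0 members passed over all genes and these 2 rose when adjusted over the list alone. Oxidative phosphorylation genes shifted by 0.037 (camera, adjusted p = 0.00396, and adjusted p = 0.339 with an estimated correlation), 24 of 32 with a positive fold change. COX7B, a subunit of cytochrome c oxidase, differed by 0.21 (adjusted p = 0.153) and was the 1 member that rose when adjusted over the list alone, and COX6A1 differed by 0.091.

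Lists that were lower with anti-PD-1 beads covered the cell cycle, ribosome biogenesis and the amino acid response. G2 and M phase genes shifted by -0.074 (camera, adjusted p = 1.66e-07), with 31 of 33 members negative, and list levels of -0.034 ± 0.019 (SD, n = 6) against 0.041 ± 0.012 (SD, n = 5) did not overlap (exact permutation p = 0.00216, adjusted p = 0.0126). The mitotic checkpoint kinase BUB1 stood at 637 ± 33.3 against 726 ± 28.7 and the mitotic kinesin KIF2C at 887 ± 35.0 against 995 ± 33.8 (both with limma adjusted p = 0.153). No member passed over all genes, and 5 fell when adjusted over the list alone. With anti-PD-1 the list level went from -0.054 on replicate 1 to -0.0028 on replicate 6, though not upward at every step. Without anti-PD-1 it lay from 0.024 to 0.052. G1 and S phase genes shifted by -0.032 (camera, adjusted p = 0.0327, and adjusted p = 0.400 with an estimated correlation), 22 of 35 negative, with the DNA polymerase subunit POLA1 at -0.23 and the replicative helicase subunit MCM7 at -0.15 (-0.050 with its other probe set), and 0 members past either adjustment. Replicate 1 with anti-PD-1 was lowest at -0.065, the other 5 lying from -0.022 to 0.0037, and without it the shift of -0.022 did not pass. MYC targets in ribosome biogenesis shifted by -0.040 (camera, adjusted p = 0.0261, and adjusted p = 0.179 with an estimated correlation). In that list DKC1, part of the pseudouridine synthase complex, differed by -0.16 and MYBBP1A by -0.25, and these 2 of 21 fell when adjusted over the list alone, while the 3 probe sets of DKC1 gave -0.16, -0.28 and 0.14. Amino acid response and ATF4 targets shifted by -0.088 (camera, adjusted p = 6.44e-05, and adjusted p = 0.179 with an estimated correlation), 20 of 23 negative, with CHAC1, a glutathione-degrading enzyme, at -0.40 and the cystine transporter SLC7A11 at -0.18 (-0.12 and 0.030 with its 2 dimmer probe sets), and 0 members past either adjustment. Its levels were lowest on replicates 1 (-0.13) and 2 (-0.079) with anti-PD-1, the other 4 lying from -0.020 to 0.0074, and highest on replicate 6 without it (0.13).

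**Figure D3:**
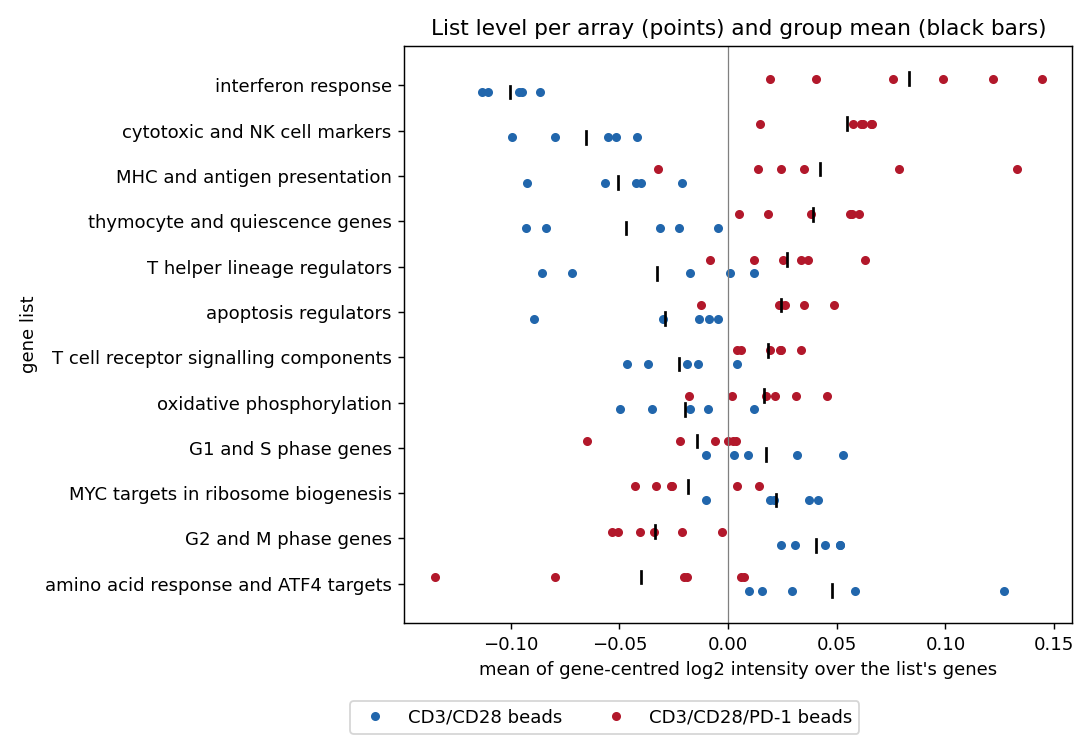
Mean of gene-centred log2 intensity (x axis) over the genes of the 12 lists past the camera threshold (y axis), 1 point per array, with anti-PD-1 (red, n = 6) and without (blue, n = 5), and black bars at group means. The interferon response levels average 0.083 with anti-PD-1 and -0.10 without, while for G2 and M phase genes they average -0.034 and 0.041.

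In all, 12 of the 29 lists passed with camera, 8 higher and 4 lower. With an estimated correlation 4 passed: interferon response and G2 and M phase genes (adjusted p = 0.0147 for both), thymocyte and quiescence genes (adjusted p = 0.0342) and cytotoxic and NK cell markers (adjusted p = 0.0304). The exact permutation test of list levels passed for 9 of the 12, and over all lists it called 3 with arrays centred on their median and 5 without replicate 5 or 6 lacking anti-PD-1.

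Of 27 genes examined that had further probe sets above the no-target level, 16 had one that gave less than 50% of the value of the brightest or the opposite sign, among them also CD58, ICAM1, TRAF3, PKM and BUB1. For BUB1 that probe set, at a mean log2 intensity of 3.56, barely cleared the no-target level. A bright one of BUB1 gave -0.20, near the -0.19 of the brightest.

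The other 17 lists did not pass with camera. Where no member of a list is said to pass when adjusted over the list alone, 0 did. Cell cycle inhibitors and p53 targets shifted by 0.052 (adjusted p = 0.0565), with BAX at 0.29 and CDKN2A at 0.16, and passed under some alternatives, such as the mean of probe sets (0.044, adjusted p = 0.0388). Activation and immediate early genes shifted by 0.052 (adjusted p = 0.0582), with IER3 at 0.17, and passed without replicate 1 lacking anti-PD-1 (0.074, adjusted p = 0.00365). Heat shock proteins shifted by -0.034 (adjusted p = 0.0959), with HSPA8 at -0.097 (-0.029 and -0.00055 with its other bright probe sets) and HSP90AB1 at -0.094, and passed with the mean of probe sets (-0.043, adjusted p = 0.0259). Sterol biosynthesis and uptake genes shifted by 0.024 (adjusted p = 0.211), with HMGCS1 at 0.15 (-0.016 with its other probe set) and FDPS at 0.12. Chemokine receptors, integrins and adhesion genes shifted by 0.016 (adjusted p = 0.296), and the adhesion ligand CD58, at 0.23, was the 1 member that rose when adjusted over the list alone. Endoplasmic reticulum stress genes shifted by -0.022 (adjusted p = 0.501), with ERN1 at -0.18 and HERPUD1 at -0.13. Cytokines and chemokines shifted by 0.015 (adjusted p = 0.560), with 9 of 27 above the no-target level. LTB, at 0.24, barely cleared that level with a mean log2 intensity of 3.57, and IL21, at -0.16, was not above it. Hypoxia response genes shifted by -0.024 (adjusted p = 0.695), with KDM3A at -0.21 and MXI1 at -0.19 among 3 that fell when adjusted over the list alone.

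The AP-1 and BATF family shifted by -0.050 (camera, adjusted p = 0.715) with members on both sides: BATF3 at 0.19, the 1 member that rose when adjusted over the list alone, and ATF3 at -0.24. Ribosomal protein genes shifted by 0.0026 (adjusted p = 0.768), with RPL11 at 0.061 and RPS13 at -0.046. Inhibitory receptors and their ligands had a mean shift of 0.0072 and a median of -0.0039 (adjusted p = 0.782), with NT5E the 1 member of 15 past the threshold over all genes and over the list alone. The 4 members at or above the median level, NT5E among them, shifted by 0.14 and passed (adjusted p = 0.0102). Anergy associated genes had a mean of -0.0038 but a median of 0.023 and a test on the higher side (adjusted p = 0.954), and SOCS2 at -0.31 was the 1 member that fell when adjusted over the list alone. NF-kappaB targets and feedback genes had a mean of 0.0067 and a median of -0.010 (adjusted p = 0.954), with ICAM1 at 0.21 and TRAF3 at -0.13. Glycolysis and glucose transport genes had a mean of 0.0084 and a median of -0.00083 (adjusted p = 0.954), with ALDOC at 0.33 and PKM at 0.10.

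Markers of monocytes, B cells, and epithelial cells and fibroblasts did not shift past the threshold, unlike the cytotoxic and NK cell list. Monocyte, macrophage and dendritic cell markers shifted by 0.017 (camera, adjusted p = 0.501), with 4 of 15 above the no-target level, CD68 at 0.14 among them, while CSF3R was not above it. B cell markers had a mean of -0.010 and a median of 0.0087 (adjusted p = 0.768), with CR2 at -0.24 the 1 member that fell when adjusted over the list alone. Epithelial and fibroblast markers had a mean of -0.0032 and a test on the higher side (adjusted p = 0.990), with 6 of 18 above the no-target level, THY1 at -0.14 among them and KRT8 not, and the 3 probe sets of THY1 gave -0.14, 0.12 and 0.021.

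No measure of array quality passed after adjustment, although principal component 1 separated the groups. The difference between 3-prime and 5-prime control probe sets was 0.28 ± 0.027 (SD, n = 6) with anti-PD-1 beads and 0.31 ± 0.065 (SD, n = 5) without for ACTB (exact permutation p = 0.459), and -0.15 ± 0.028 against -0.17 ± 0.025 for GAPDH (exact permutation p = 0.229). The 18S ribosomal RNA controls had a mean log2 intensity of 11.81 ± 0.37 against 11.24 ± 0.88 (exact permutation p = 0.171) and the bacterial hybridisation controls 9.82 ± 0.26 against 9.64 ± 0.17 (exact permutation p = 0.232). Principal component 1, which held 21.0% of the variance, scored 3.63 ± 5.19 with anti-PD-1 beads and -4.35 ± 1.52 without (exact permutation p = 0.00649, adjusted p = 0.0584 over 9 measures). On replicates 1 to 6 with anti-PD-1 the scores were 12.6, 4.80, 5.06, 1.49, -0.30 and -1.89, a fall over most steps. Without anti-PD-1 the score was lowest on replicate 1 at -6.28 and highest on replicate 4 at -2.82. All 6 scores with anti-PD-1 thus lay above all 5 without. Correlations between arrays ran from 0.997 to 0.999, and no pair of arrays was identical.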

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

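Of 222 groups of values examined for a sample standing apart from the rest of its group, 15 had one, and chance gives about 5%, or 1 in 20 groups. The tests with covariates and of NK transcripts were chosen after the gene and list results were seen. The covariate tests were chosen before their own results. The NK transcripts belong to the cytotoxic and NK cell list, whose results had been seen, so the bound for them was not set blind. The condition under which a covariate counts as a test was added after the results were seen, and its measure was changed from genes tied to genes moved after both shares were known. The case of hybridisation turned on that change and is therefore left open. The confidence limits for the NK transcripts were also added after their rises were seen.

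Among genes past the threshold, ENPP1 was highest on replicate 5 with anti-PD-1 at a log2 intensity of 10.04, where the other 5 lay from 9.81 to 9.89, and TAP1 was lowest on replicate 3 with anti-PD-1 at 7.01, the others lying from 7.26 to 7.41. On replicate 1 with anti-PD-1, KIF2C at 9.67 and HERPUD1 at 8.69 lay below the other arrays of the group. ICAM1 was high on replicate 4 with anti-PD-1 at 5.38, and MYBBP1A was high on replicate 5 at 6.88. Without anti-PD-1, replicate 6 stood highest for EFEMP1 at 9.87, ATF3 at 8.53 and CHAC1 at 8.63. Replicate 3 without anti-PD-1 was apart for NFATC1 at 8.12, IL2 at 3.21, the bacterial probe sets without a target at 3.09 and principal component 2 at -7.63. KRT8 was low on replicate 5 without anti-PD-1 at 3.32, a level near that of probes without a target. The cytotoxic and NK cell list was lowest on replicate 6 with anti-PD-1 at 0.015, the others lying from 0.057 to 0.066. Outside the named genes, 4 probe sets without a symbol in the annotation used here passed the threshold, 3 higher (by 0.99, 0.69 and 0.37) and 1 lower (-0.26), as did 1 with several symbols (0.33).

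The first pattern weighed was the 29 genes past the threshold between the bead types. In 100 of the 462 splits of the 11 arrays into 6 and 5, only 1 gave as many genes, the real one, and the highest of the others gave 1. A chance division of these arrays is therefore unlikely, as far as 100 splits can show and if the arrays are independent. A handling difference that ran along with the bead type stays open, since the labels give no batch. Principal component 1 separated the groups, and within the anti-PD-1 arrays it fell over most steps of the replicate number. The labels do not say what these numbers mean, so an effect of order was not tested.

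The second pattern was the rise of the interferon response list, with a mean shift of 0.18. If uneven hybridisation were behind it, the shift should fall below 50% of its value with the hybridisation controls as a covariate, but it was 0.182 (adjusted p = 1.09e-15), and 0.180 with the GAPDH difference between 3-prime and 5-prime probe sets as a covariate. Both values met the bound set in advance, which counts only if the covariate moves other genes. The hybridisation controls were tied to 8.41% of genes at an unadjusted p under 0.05 and moved 388 by more than their standard error. Of 200 reorderings within the groups and the real order, a share of 0.0597 tied as many and 0.0398 moved as many. For GAPDH these were 3.99%, 85 genes, 0.836 and 0.856. By genes moved the hybridisation covariate met that condition narrowly, and by genes tied it did not. Since the measure was changed after both shares were known, these values cannot decide, and uneven hybridisation remains open. The GAPDH covariate moved no more than its reorderings, so RNA quality remains open, as do PD-1 engagement itself and an unrecorded batch.

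The third pattern was the rise of GZMB and GZMA. Admixed NK or cytotoxic cells would bring their abundant transcripts along, and the largest rise among 10 such transcripts was 9.44 intensity units (NKG7, 0.22 on the log2 scale, adjusted p = 0.227). NKG7 also rose when adjusted over the cytotoxic and NK cell list alone. The mean shift of the 10 transcripts was 0.028 on the log2 scale (exact permutation p = 0.312), and 0.063 over the 5 of 10 above the no-target level (exact permutation p = 0.156). The bound was 94.1, a share of the rise of GZMB (377), and the highest upper 95% limit among the 10 was 16.1. Intensities of different probe sets are not on a common scale, and only 5 of the 10 were above the no-target level. No conclusion is therefore drawn from that bound. On the log2 scale, where each probe set is held against itself, the highest upper limit was 0.35 and the lower limit of GZMB 1.07, although transcripts that are dim in these cells would show added ones more readily. The lower limit of GZMA, 0.28, lay below that highest upper limit. For GZMB the log2 values argue against admixed NK or cytotoxic cells that carry such transcripts as the whole cause. That reading is weakened because the list holding these transcripts had been seen beforehand. For GZMA the values cannot decide, and admixture remains open. Cells lacking such transcripts, an unrecorded batch and a rise within the Jurkat cells remain open for both genes.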

How the results depend on the processing

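All 29 genes past the threshold kept their direction under every alternative, except that 1 was not tested with the filter on level. The interferon response list (0.171 to 0.237 over 20 alternatives, adjusted p at most 0.0147) and GZMB (1.17 to 1.24 over 23, adjusted p at most 0.000145) stayed past it. The 18S and hybridisation covariates were chosen after seeing the data. Total, higher and lower genes were 69, 48 and 21 with the filter, which tests fewer genes, 112, 72 and 40 with trend and robust variances (all 29 shared), 7, 7 and 0 with a minimum fold change, and 16, 16 and 0 with the 18S covariate. Lower genes were 3 with centring, 4 with the mean of probe sets, 4 with every probe set and 2 with array weights. With the replicate number as a block, total, higher and lower genes were 9, 9 and 0, all 9 shared, from fewer arrays and residual degrees of freedom. Same-numbered arrays did not deviate together (correlations from -0.11 to -0.051, no array best matched by its own number). That cannot show that the samples were unpaired, since the labels do not say what the numbers mean. Leaving out 1 array gave 16 to 30 genes, 15 to 27 higher and 0 to 4 lower: 18 without replicate 2 with anti-PD-1, and 16, 17, 19 and 16 without replicates 3, 4, 5 and 6 lacking it. An estimated correlation left 4 lists, ending the calls of ATF4 targets (-0.088, also with fry), MHC (0.093), oxidative phosphorylation (0.037, also with fry), T helper regulators (0.059), T cell receptor signalling (0.041), MYC targets (-0.040), G1 and S phase (-0.032, also with fry) and apoptosis (0.053). G1 and S phase genes also did not pass with the block (-0.030), the filter (-0.033) or the hybridisation covariate (-0.019), nor without replicate 1 with anti-PD-1 (-0.022) or replicates 1 (-0.028) and 5 (-0.023) lacking it (-0.039 to -0.022 without 1 array). MYC targets did not pass with the block (-0.039) or the filter (-0.040), nor without replicates 5 and 6 with anti-PD-1 (-0.035 and -0.037) or 5 lacking it (-0.035; -0.048 to -0.035 without 1 array). Apoptosis did not pass with the mean of probe sets (0.038), the filter (0.049) or the 18S covariate (0.034), nor without replicates 3 and 6 with anti-PD-1 (0.049 and 0.053) or 3 lacking it (0.038; 0.038 to 0.061 without 1 array). T cell receptor signalling did not pass without replicate 6 with anti-PD-1 (0.040) or 6 lacking it (0.035; 0.035 to 0.048 without 1 array). Exact tests of list levels called 3 lists with centring, 14 with the filter and 5 to 10 without 1 array, 5 without replicate 5 or 6 lacking anti-PD-1. Lists that passed only under an alternative were inhibitory receptors with the filter, which left 4 members (0.14), cell cycle inhibitors with the block (0.051), centring (0.050), the mean of probe sets (0.044), the hybridisation covariate (0.062) and without replicates 1, 4 and 5 with anti-PD-1 (0.055, 0.052 and 0.064) or 1 and 4 lacking it (0.058 and 0.062), activation genes with centring (0.050) and without replicates 1 and 4 with anti-PD-1 (0.054 and 0.057) or 1 lacking it (0.074), and heat shock proteins with the mean of probe sets (-0.043). Among named genes, the replicate block ended 11 calls (CST7, GZMA, HLA-E, IRF1, LAT, MON1B, NT5E, STAT4, TAP1, TIMP1 and TNFSF10), the minimum fold change 12, the 18S covariate ended 7 calls (CST7, HLA-E, IRF1, LAT, MON1B, NT5E and STAT4) and the hybridisation covariate 3 (CST7, MON1B and STAT4), and CST7 was also lost with the random block (0.27, adjusted p = 0.0602) and with every probe set (adjusted p = 0.0576). Signs turned in results that never passed: anergy genes with quantile normalization (0.0012), the mean of probe sets (0.000243), the 18S covariate (0.0053) and without 1 array (-0.015 to 0.0071); epithelial markers with the mean of probe sets (0.00560), the 18S covariate (0.0125) and without 1 array (-0.013 to 0.011); NF-kappaB targets with the filter (-0.013); ribosomal proteins without 1 array (-0.0022 to 0.0090); and CD3E with the hybridisation covariate (0.0090) and without 1 array (-0.043 to 0.011). Apart from the filter, the cause was not tested. Dim signal limits IL2, IL2RA and most cytokines.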

Other observations

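The gene sets in this part and their tests were chosen after the gene-level results were seen, and 8 such sets were compared. Class I antigen processing genes shifted by 0.19 on the log2 scale (exact permutation p = 0.00216, adjusted p = 0.0173), with levels of 0.088 ± 0.046 (SD, n = 6) with anti-PD-1 beads and -0.11 ± 0.024 (SD, n = 5) without. PSMB9, PSMB10 and TAP1 were the 3 of 13 members past the threshold over all genes, PSMB10 rising by 0.32. The other immunoproteasome subunit PSMB8 differed by 0.22 (adjusted p = 0.0751) and the activator subunit PSME2 by 0.24 (adjusted p = 0.0751). PSMB8, PSMB9 and TAP1 are also in the interferon response list. These 3, PSMB10, PSME1, PSME2 and TAP2 are also in the gamma type set below. The shifts of these sets are therefore not separate results. The 14 constitutive proteasome genes shifted by 0.027 (exact permutation p = 0.0823, adjusted p = 0.110).

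Metallothioneins, small metal-binding proteins, shifted by 0.13 (exact permutation p = 0.00866, adjusted p = 0.0173), all 8 measured members having a positive fold change. MT1X rose by 0.30 from 431 ± 21.7 to 530 ± 37.9, a call that held in 1 of 11 fits without an array, while MT2A at 0.17 did not pass over all genes (adjusted p = 0.153), and probe sets of this family can share sequence. Genes of interleukin 2 family signalling shifted by -0.033 (exact permutation p = 0.0411, adjusted p = 0.0658), and the 11 of 15 above the no-target level by -0.017 (exact permutation p = 0.258). Interferons and their receptors shifted by -0.027 (exact permutation p = 0.147, adjusted p = 0.168), and IFNG, IFNB1 and IFNA2 were not above the no-target level on average over the arrays.

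Among interferon-induced genes, 20 of a gamma type shifted by 0.17 (adjusted p = 0.0173) and 25 of type I by 0.076 (adjusted p = 0.0173). Over all genes 5 of the 20 and 2 of the 25 were higher past the threshold. Other gamma type members did not rise, such as WARS1 at -0.075 and the dim CIITA at -0.095. Both sets share members with the interferon response list, GBP1 and IRF1 among those of gamma type. The difference between members above the no-target level was 0.14 (exact permutation p = 0.00216, the smallest possible), with 16 genes against 23, but the leading genes had been seen when the sets were written. One hypothesis is that the response may be of a gamma type rather than type I. Among genes with an adjusted p of 0.1 or more, 9 of gamma type and 20 of type I, the difference was 0.0109 (exact permutation p = 0.753). That threshold itself takes out the genes that changed, so this test cannot decide, and with no independent genes the hypothesis stays open.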
